A study of Mus musculus with 2 samples.

How the data were processed

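Total RNA longer than 200 nt was profiled in limb tissue of mouse embryos (strain B6NCrl, pools of both sexes) at embryonic day 10.5. There was 1 group of 2 biological replicates: replicate 1 was a pool from 69 embryos and replicate 2 a pool from 51 embryos. Per the labels, RNA was extracted with the mirVana method, 10 ng entered each library, and synthetic spike-in RNAs were added. The labels' protocols link a manual of the SMARTer Ultra Low RNA kit. The labels give no contrast between groups, so levels within the tissue were described and the 2 libraries were compared with each other.

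The deposited gene tables hold expected counts (estimated reads per gene, which need not be whole) and TPM (length-normalised abundance scaled over every row, spike-ins and mitochondrial genes included). They also hold a posterior mean TPM with interval bounds, whose level is not stated in the tables (95% was assumed beforehand). The deposited transcript tables give the same quantities per transcript, and the percent of the gene's TPM that each transcript takes. Per the sample text files, the tables were quantified from transcriptome alignments on mm10 with the GENCODE M4 annotation, each library on its own. The aligner, the quantifier and their versions are not given in the sources used here, nor whether counting used strand. Effective length in the tables was the transcript length minus 99 nt, so the TPM of very short RNAs rests on few read positions. Reads shared by near-identical genes were divided among them by the estimate, so globin pairs, histone copies, pseudogenes and the 7SL RNA genes Rn7s1 and Rn7s2 are uncertain one by one, as are overlapping antisense genes.

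A gene table had 69691 rows: 43346 with Ensembl identifiers, 96 for spike-in RNAs of the ERCC set and the rest for numeric identifiers and phiX. The 26248 rows with numeric identifiers are not named by any source used here, and 26185 of them are under 100 nt. They stayed out of library sizes and tests. Gene symbols, biotypes and coordinates came from GENCODE M21 on GRCm38 (the same assembly as mm10), matched by identifier without version. This named 42462 Ensembl rows (98.0%), and the unnamed rows held 0.30% and 0.29% of gene counts in replicates 1 and 2.

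Expected counts summed to 40509328 in replicate 1 and 43983028 in replicate 2. Expected counts were rounded to whole numbers for edgeR 4.0.16 (R 4.3.3), which gave TMM scaling, log2 CPM with a prior count of 2, and the common biological coefficient of variation from an intercept-only model. DESeq2 1.42.0 size factors served as the other scaling. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A gene counted as expressed at a TPM of 1 or more in both libraries. Values are the mean ± SD over 2 libraries.

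Gene lists (44, covering limb patterning, signalling, tissues and other cell types), 32 gene pairs and the tests of these lists and pairs were fixed before the data were examined. The level of a list was the median over its members of log2(TPM + 1), set against 10000 random lists of protein-coding genes of the same size, and called high or low at percentiles 97.5 and 2.5. For a difference between libraries, the median log2 difference (replicate 2 minus replicate 1) over members with a mean expected count of 10 or more was set against 10000 random lists matched on mean expression in 20 bins. Lists needed 3 members past that filter, which 43 lists had. Random lists hold unrelated genes, whereas members of a fixed list can vary together and some lists share genes. Chance places 5% of unrelated lists outside the percentiles, and no adjustment for the number of lists was made. A gene pair was called where the tables' TPM intervals of its genes did not overlap, in the same direction, in both libraries. Hox paralog groups 9 to 13 and 1 to 8 were compared within each of 4 clusters by a two-sided exact permutation test over genes, with Benjamini-Hochberg adjustment over 4. With 2 libraries, an exact two-sided sign-flip test of any one value cannot give a p below 0.5, so no p-value is given for differences between the libraries. Each library is also 1 pool, so pool, library and any batch cannot be separated.

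Genes named in the text were set by a fixed rule: key limb genes and pair members, the 10 highest genes outside the mitochondrial genome, up to 4 highest members and the lowest member of each list, and the 5 genes with the largest and the 5 with the smallest log2 difference at a mean count of 100 or more. Any Hox gene could be named. Not every gene the rule allows is named. Other list members named in the text were chosen after their values were seen. Per-gene intervals (exact binomial, 95%, on rounded counts after TMM scaling), the percentile of a gene among 500 genes of like expression, counts of 2-fold differences and the scaling to spike-in counts were added after seeing the data. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

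The alternatives tried were other expression cutoffs, pseudocounts, count filters and prior counts, posterior mean TPM, DESeq2 size factors, matching on length, rescaled TPM, exact binomial intervals for pairs and each library alone. Steps were tested on simulated data. For counts drawn with a coefficient of variation of 0.1 over 16668 genes, the estimate was 0.099, and it was 0.148 once 200 genes had been changed by 2 on the log2 scale. With 200 of 16860 simulated genes changed by 1 on the log2 scale, lists of 12 genes drawn from the raised genes were called in 100% of 200 draws and unchanged lists in 7.50%, against a nominal 5%. Every member of a raised list was changed, so these rates do not carry over to fixed lists with mixed members or smaller differences. The permutation test on 200 simulated sets called 2.50% of sets with no difference and 86.0% of shifted sets.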

Results

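Limb buds at embryonic day 10.5 hold mesenchyme, a covering ectoderm with its apical ridge, blood vessels, blood cells and muscle precursors that enter from the somites. Total RNA of this tissue was measured in 2 pools, replicate 1 from 69 embryos and replicate 2 from 51 embryos. Expected counts totalled 40509328 and 43983028. Protein-coding genes took 95.9% and 96.1% of gene counts, mitochondrial genes 0.893% and 0.997%, and ribosomal RNA genes 0.161% and 0.176%. Mitochondrial ribosomal RNA genes belong to both of the last shares. The ribosomal share covers only rows annotated as such and need not measure all ribosomal RNA in the libraries. Spike-in RNAs took 3.89% and 3.45% of all counts. Of 96 spike-ins, 83 had counts in both libraries, and the 27 with a mean count of 1000 or more had an SD of 0.039 in their log2 difference between libraries.

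The first question was which genes the tissue used. At a TPM of 1 or more in both libraries, 13489 genes were expressed, of which 11853 were protein-coding. Outside the mitochondrial genome, the highest levels belonged to the cytoskeletal actin Actb at 6064 ± 204 TPM (SD, n = 2, as for all values given with ±), the embryonic beta-globin Hbb-y at 5689 ± 458, the histone gene Hist1h2ap at 5618 ± 75.3, the cyclophilin gene Ppia at 5263 ± 489 and the ferritin gene Ftl1 at 4397 ± 228. Among the 10 highest genes outside it were also the 7SL RNA genes Rn7s1 (4667 ± 20.6) and Rn7s2 (4667 ± 20.9), the pseudogenes Gm28437 (5015 ± 481) and Gm10123 (4244 ± 328), and the microRNA row Gm22133 (4804 ± 369). Rn7s1 and Rn7s2 share reads, and pseudogenes can share reads with their parents. The TPM interval of Gm28437 ran from 662 to 4670 in replicate 1 and from 1441 to 5503 in replicate 2. Gm22133 rests on only 1211 and 1407 counts over a very short effective length. It lies inside Ftl1 on the same strand, so these can be reads of Ftl1.

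Limb transcription factors stood at high levels. All 22 members of the mesenchyme list were expressed, with a median of 30.6 TPM against 21.3 for expressed protein-coding genes. Msx1 led at 307 ± 5.86 TPM, followed by Prrx1 at 162 ± 30.1, Prrx2 at 106 ± 18.1 and Shox2 at 97.0 ± 18.2, while Tbx2 was lowest at 3.91 ± 0.771. Proximal genes had a median of 54.2 TPM, with Meis1 at 95.8 ± 6.63, Meis2 at 54.2 ± 1.89 and Pbx3 at 25.9 ± 1.25. Distal genes had a median of 28.4 TPM and ranged from Hoxa11 at 61.4 ± 1.70 to Hoxa13 at 5.77 ± 4.97. The forelimb gene Tbx5 (ENSMUSG00000018263.8, chromosome 5, 119832668 to 119885219) was at 27.6 ± 1.68 TPM. The hindlimb genes Tbx4 (ENSMUSG00000000094.8, chromosome 11, 85886422 to 85916097) and Pitx1 (ENSMUSG00000021506.7, chromosome 13, 55825051 to 55836192) were at 30.4 ± 15.2 and 95.8 ± 43.5, and Isl1 was at 10.4 ± 1.18. The forelimb list had a median of 9.66 TPM, and the hindlimb list medians of 17.9 and 41.1 in replicates 1 and 2.

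Signalling genes spanned a wide range. Fgf8, made by the apical ridge, was at 77.2 ± 16.0 TPM and Fgf10, made by the mesenchyme, at 12.9 ± 3.73, whereas the ridge gene Fgf4 was at 2.00 ± 0.997. Shh (ENSMUSG00000002633.3, chromosome 5, 28456815 to 28467256), which a small posterior region makes, was at 0.880 ± 0.269 TPM with 74.0 and 49.7 counts, while its pathway members Gas1, Smo, Gli3 and Boc were at 128 ± 10.9, 54.3 ± 0.941, 51.3 ± 4.03 and 24.6 ± 11.0. Hand2 and Alx4, posterior and anterior factors, were at 8.63 ± 0.141 and 11.4 ± 1.41 TPM. The dorsal genes Lmx1b and Wnt7a were at 10.4 ± 1.70 and 5.57 ± 2.07, and the ventral ectoderm gene En1 at 0.815 ± 0.0636. FGF response genes had a median of 33.4 TPM, led by Dusp6 (173 ± 8.57) and Fgfr1 (97.4 ± 13.6). BMP pathway genes had a median of 30.3, led by Id3 (356 ± 61.0) with Nog lowest at 0.440 ± 0.424. The WNT list had a median of 13.7 TPM, led by Ctnnb1 at 420 ± 60.7 and Wnt5a at 65.9 ± 16.3. Retinoic acid genes had a median of 23.9, led by the binding proteins Crabp2 (841 ± 69.1) and Crabp1 (615 ± 141), with the degrading enzyme Cyp26a1 at 3.06 ± 0.431. The sonic hedgehog list and the apical ridge list had medians of 11.3 and 4.81 TPM.

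**Figure D1:**
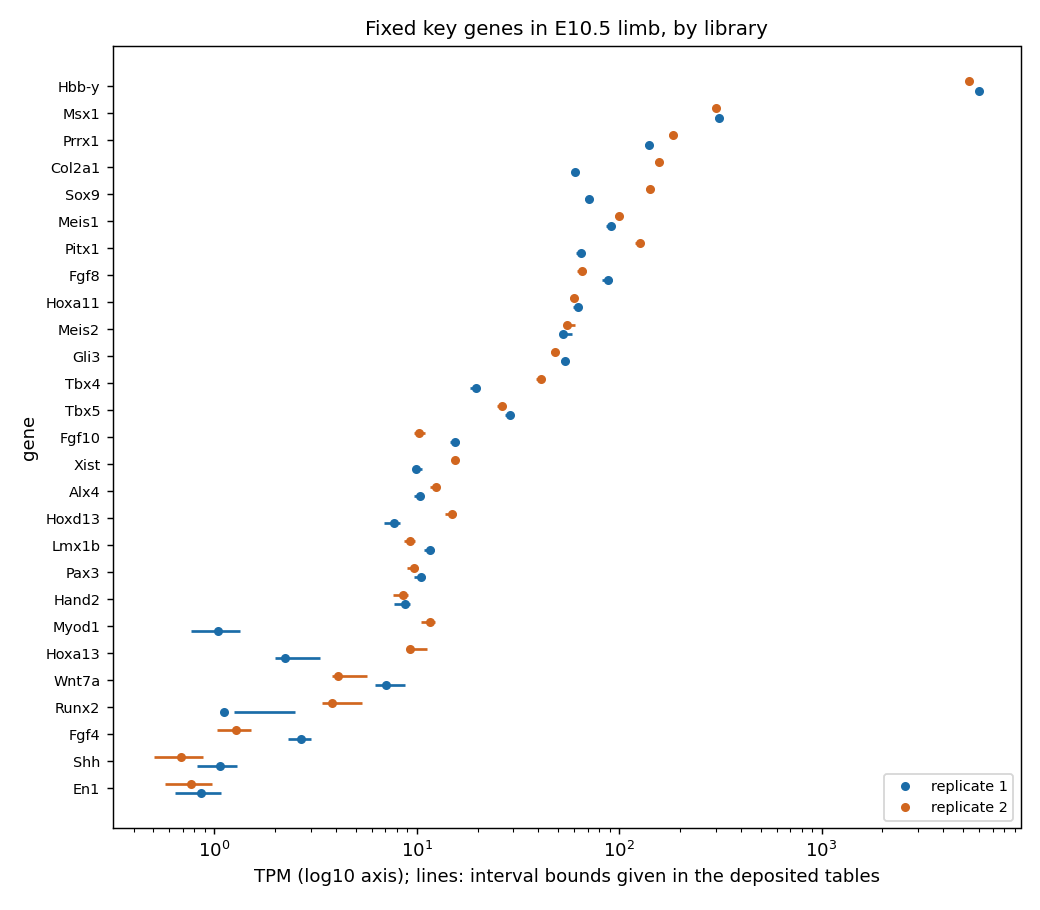
TPM of the fixed key genes on a log10 axis, 1 point per library, with lines for the interval bounds in the deposited tables, which belong to the posterior mean and can leave the point outside. Myod1, Col2a1 and Hoxa13 lie further right in replicate 2, at 11.6, 158 and 9.28 TPM against 1.05, 60.6 and 2.25 in replicate 1.

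Gene lists of differentiated tissues spanned a wide range. Cartilage genes had medians of 4.78 and 10.7 TPM in replicates 1 and 2, with Col2a1 (109 ± 68.6), Sox9 (106 ± 49.9), Col9a1 (51.3 ± 23.8) and Sox5 (37.0 ± 15.9) highest and Matn1 lowest at 0.0950 ± 0.134. Bone genes were low, with medians of 0.360 and 0.145 TPM in the 2 libraries, Runx2 at 2.47 ± 1.91 and Alpl at 5.47 ± 1.63. Myogenic regulators had a median of 7.93 TPM, with Pax3 at 10.1 ± 0.580 and Myf5 at 9.88 ± 4.00, and muscle structure genes medians of 1.01 and 2.12 in the 2 libraries, led by Actc1 at 15.7 ± 10.4. The somite and sclerotome list had a median of 7.69 TPM, led by Meox2 (28.5 ± 11.5) and Tcf15 (23.9 ± 1.58). Matrix genes had a median of 43.5 TPM, led by Col3a1 (344 ± 70.7), Col1a2 (152 ± 85.2) and Fn1 (134 ± 37.4), with Has2 at 0.925 ± 0.0212.

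Lists of other cell types ranged from high to near 0. Endothelial genes had a median of 21.2 TPM, with Egfl7 at 81.2 ± 0.735 and Pecam1 at 22.9 ± 1.80, and all 13 members were expressed. Erythroid genes had a median of 37.2, led by Hbb-y, Hba-a2 (3050 ± 157), Hbb-bh1 (2563 ± 791) and Hba-x (2331 ± 281). Surface ectoderm genes had a median of 17.6 TPM, led by Krt18 (35.6 ± 9.66), Epcam (33.8 ± 2.43) and Krt8 (32.7 ± 8.46). Macrophage genes had a median of 2.73 TPM (C1qb 8.88 ± 0.00707), neural crest and glia genes 1.05 (Kit 10.2 ± 0.799), neuron genes 2.44 (Tubb3 6.18 ± 0.587) and heart genes 2.52 (Myl7 6.22 ± 0.707). Liver genes had a median of 0.230 TPM and neural tube genes 0.0300, with Sox2 the highest of the latter at 0.110 ± 0.0424. At a TPM of 1 or more in both libraries were 8 of 11 macrophage, 4 of 9 neural crest and glia, 6 of 9 neuron, 5 of 8 heart, 2 of 7 liver and 0 of 7 neural tube genes, and none of these lists was called high.

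Growth genes were among the most abundant groups. Ribosomal protein genes had a median of 766 TPM, led by Rpl41 at 3070 ± 183, glycolysis genes 563, led by Eno1 at 3029 ± 585, and proliferation genes 240, led by Cdk1 at 462 ± 6.97 with Mki67 at 35.5 ± 5.59. Early embryonic RNA-binding and related genes had a median of 116 TPM, led by Igf2bp2 (169 ± 0.113) and Mycn (165 ± 51.1). Imprinted genes had a median of 218, led by Mest (2999 ± 406) and Igf2 (682 ± 63.0), and mitochondrial messenger RNAs 716, led by mt-Atp6 (4855 ± 397). Polyadenylated histone genes had a median of 568 TPM, led by H2afz (2795 ± 114), and replication histone genes 5.17. How well the libraries captured RNAs without poly(A) tails was not tested, so these medians need not compare as tissue levels. The cyclin-dependent kinase inhibitor list had a median of 7.84 TPM, led by Cdkn1c at 281 ± 121, while Cdkn2a had no counts. Nuclear noncoding RNAs had a median of 11.3, led by Malat1 at 2077 ± 589. RNAs without poly(A) tails had a median of 24.6, with Rn7sk at 79.6 ± 13.4, and early response genes 1.89, with Ier2 at 179 ± 17.3. Xist was at 12.7 ± 3.92 TPM and the Y-linked gene Eif2s3y at 22.8 ± 0.813, in pools of both sexes, and the sex chromosome list had a median of 13.2.

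Against random lists of protein-coding genes, 13 of 44 lists lay within the top 2.5%: limb mesenchyme, proximal, FGF response, BMP, erythroid, proliferation, polyadenylated histone, imprinted, mitochondrial, glycolysis, matrix, early embryonic and ribosomal protein lists. None lay within the bottom 2.5%. Against expressed genes alone, with list members limited likewise, the mesenchyme, proximal, FGF response, BMP, erythroid and matrix lists were no longer called. Then 8 lists lay low: apical ridge, Hoxa cluster, replication histone, bone, macrophage, neural crest and glia, neuron and heart lists. With posterior mean TPM, median log2(TPM + 1) was 10.40 against 9.45 for mitochondrial genes, 1.74 against 1.00 for neural crest and glia, 0.39 against 0.25 for bone and 0.08 against 0.04 for the neural tube list, which was then called low.

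Posterior Hox genes dominated 2 of the 4 clusters. Hox genes are numbered along each cluster, and the high numbers pattern the limb. In the Hoxa cluster, paralogs 9 to 13 exceeded paralogs 1 to 8 by 3.05 in mean log2(TPM + 1), with adjusted p = 0.0317 (two-sided exact permutation test over 11 genes). In the Hoxd cluster the difference was 3.03, with adjusted p = 0.0317 (exact permutation test over 9 genes). Hoxa10 at 146 and 164 TPM in replicates 1 and 2 and Hoxa9 at 92.3 ± 16.0 led the former, and Hoxd10 at 49.9 ± 9.83 and Hoxd9 at 37.8 ± 8.30 the latter. In the Hoxb and Hoxc clusters the differences were -0.90 and -1.02, with adjusted p = 0.422 and 0.392 in the exact permutation test. Hoxb2 led its cluster at 10.4 ± 1.20 TPM, Hoxc10 led its own at 30.5 ± 17.9, and Hoxb13 had no counts. Genes of a cluster are not independent replicates. In replicate 1 alone, the Hoxa and Hoxd differences were 2.85 and 2.69, each with adjusted p = 0.0606 in the exact permutation test, above the 0.05 threshold, and without genes under a TPM of 0.1 the Hoxb difference was 0.10.

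**Figure D2:**
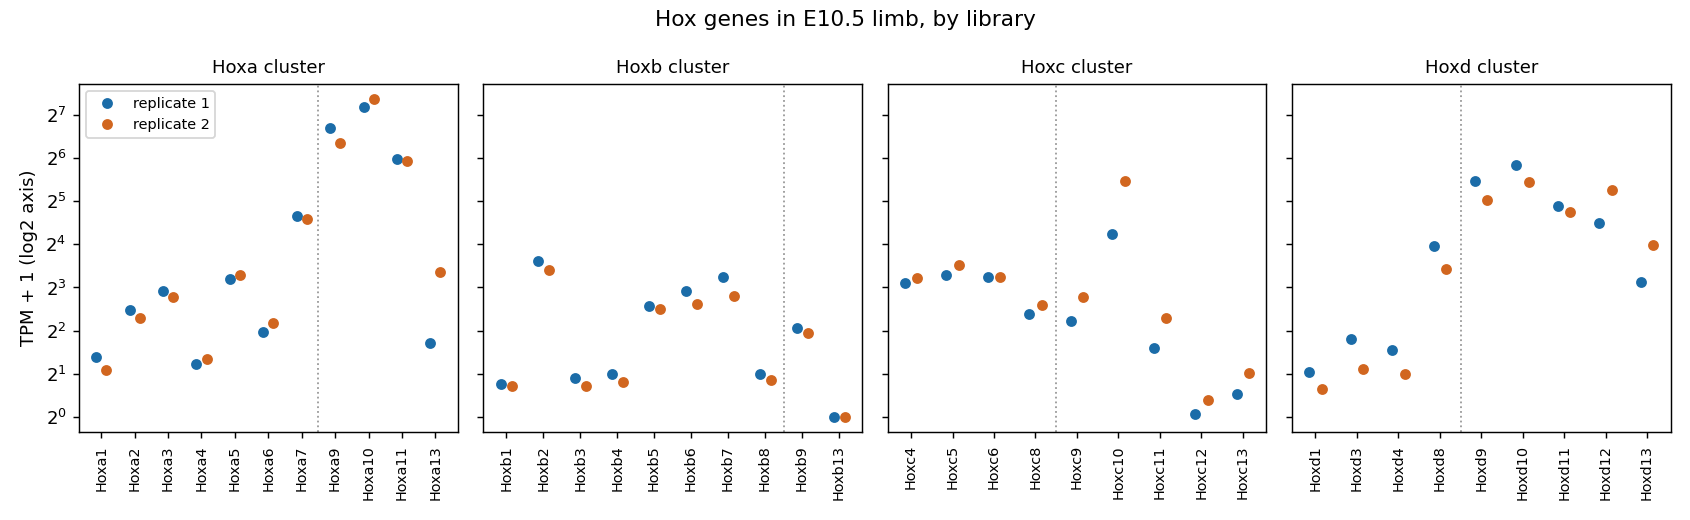
TPM + 1 of each Hox gene on a log2 axis, 1 point per library, with a dotted line between paralogs 8 and 9 of each cluster. Genes right of the line stand higher in the Hoxa and Hoxd clusters, by 3.05 and 3.03 on the log2 scale.

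The fixed gene pairs asked which partner was the more abundant, and 26 of 32 were called in both libraries. Among signals, Fgf8 exceeded Fgf4 40.9-fold (log2 5.36 ± 0.45) and Fgf10 6.03-fold, Bmp4 exceeded Bmp2 13.2-fold, Wnt5a exceeded Wnt7a (log2 2.95 in replicate 1 and 4.24 in replicate 2), and the receptor Ptch1 exceeded its ligand Shh 13.6-fold. Among factors, Gli3 exceeded Gli1 (log2 2.59 ± 0.04) and Hand2 (5.93-fold), Alx4 exceeded Hand2 1.32-fold, Msx1 exceeded Msx2 9.96-fold, Lhx9 exceeded Lhx2 2.75-fold, Lmx1b exceeded En1 12.7-fold, Meis1 exceeded Meis2 1.77-fold and Prrx1 exceeded Prrx2 1.53-fold. Among Hox genes, Hoxa11 exceeded Hoxa13 (log2 4.80 in replicate 1 and 2.70 in replicate 2), Hoxd11 exceeded Hoxd13 2.55-fold, Hoxd13 exceeded Hoxa13 2.35-fold, Hoxa9 exceeded Hoxd9 2.45-fold and Hoxc10 exceeded Hoxc5 2.89-fold. Pitx1 exceeded Tbx5 3.29-fold. Sox9 exceeded Runx2 48.5-fold, a log2 ratio of 5.60, or 5.12 with posterior mean TPM. That ratio was 5.99 in replicate 1 and 5.21 in replicate 2. Fgfr1 exceeded Fgfr2 (log2 1.07 in replicate 1 and 0.93 in replicate 2) and Rarg exceeded Rarb 5.91-fold. Cyp26b1 exceeded Aldh1a2 1.56-fold and Igf2 exceeded H19 1.64-fold. The embryonic globins Hbb-y and Hba-x exceeded Hbb-bs 190-fold and Hba-a1 1.45-fold, with reads shared among globin copies. Each pair took a single copy, leaving out Hbb-bt and Hba-a2. Hba-a2 itself stood above Hba-x, so the alpha-globin pair does not rank Hba-x above the Hba-a genes together. The other pairs were not called: the log2 ratio of Tbx5 to Tbx4 was 0.55 in replicate 1 and -0.64 in replicate 2, that of Pax3 to Myod1 was 3.32 in replicate 1 and -0.26 in replicate 2, and that of Krt18 to Krt14 was 2.67 in replicate 1 and 0.09 in replicate 2. Ratios of Sox9 to Col2a1, Col1a1 to Col2a1 and Lin28b to Lin28a were 0.04 ± 0.27, -0.34 ± 0.72 and 0.47 ± 0.74 on the log2 scale.

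The remaining comparison the design allows is pool against pool. Across 16860 genes with a mean count of 10 or more, log2(TPM + 1) of the libraries correlated with Pearson r = 0.992 and Spearman rho = 0.989, across genes, which are not independent replicates. The common biological coefficient of variation was 0.170. Counts of the libraries differed by more than sampling noise, with a chi-square of 41.2 per degree of freedom, so they are not a single library deposited again. Of 12254 genes with a mean count of 100 or more, 155 were at least 2-fold higher and 40 at least 2-fold lower in replicate 2, and the counting interval excluded equality for 7721 (63.0%).

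Cartilage, muscle, bone, hindlimb and distal lists were higher in replicate 2 by the median log2 difference of their members, not in every member. Of the cartilage genes, 11 of 12 measured members were higher, with a median log2 difference (replicate 2 minus replicate 1) of 0.84 against -0.17 to 0.16 for 95% of random lists of like expression. Col2a1, the main cartilage collagen (ENSMUSG00000022483.12, chromosome 15, 97975602 to 98004695), differed by 1.18 (1.14 to 1.21), with a 95% exact binomial counting interval as for the genes below, Sox9 by 0.85 (0.81 to 0.89), Col9a3 by 3.02 (2.80 to 3.27) and Col9a2 by 3.22 (2.85 to 3.71), whereas Hapln1 was lower at -0.35 (-0.44 to -0.27). Muscle structure genes had a median of 1.32 (-0.25 to 0.48), or 0.46 with deposited TPM, with 7 of 9 higher, including Actc1 (1.32, 1.14 to 1.52) and Tnnt1 (1.94, 1.56 to 2.39). Myogenic regulators had a median of 0.40 (-0.18 to 0.31) with 6 of 9 higher. Myod1 (ENSMUSG00000009471.3, chromosome 7, 46376474 to 46379099) differed by 3.28 (2.90 to 3.78) and Myog by 2.83 (2.48 to 3.27), while the precursor genes Pax3 and Lbx1 were at -0.26 (-0.39 to -0.13) and -0.82 (-1.08 to -0.58). The somite and sclerotome list had a median of 0.87 (-0.20 to 0.35) and 5 of 8 higher, with Pax1 at 2.00 (1.75 to 2.29) and Tbx18 at 1.04 (0.94 to 1.13), but Tcf15 at -0.01 (-0.18 to 0.16) and Meox1 at -0.02 (-0.19 to 0.15). Bone genes had a median of 1.15 (-0.33 to 0.64) and 3 of 5 members higher, with Runx2 at 1.52 (1.23 to 1.85) and Spp1 at 1.55 (1.15 to 2.03). This call was lost with deposited TPM (0.15) and without the count filter (0.10). The median TPM of the whole bone list was 0.360 in replicate 1 and 0.145 in replicate 2.

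Hindlimb genes were higher in 5 of 5 cases, with a median of 0.79 (-0.23 to 0.28): Tbx4 at 0.94 (0.85 to 1.02), Pitx1 at 0.78 (0.73 to 0.84) and Hoxc10 at 1.12 (1.01 to 1.24), with Isl1 at 0.14 (-0.04 to 0.31). The forelimb list stayed inside the random range at -0.02, and its member Tbx5 was at -0.27 (-0.34 to -0.19). Distal genes had a median of 0.53 (-0.20 to 0.21) with 4 of 6 higher. Hoxa13 (ENSMUSG00000038203.14, chromosome 6, 52257694 to 52260880) differed by 2.24 (1.97 to 2.58), Hoxd13 by 0.81 (0.65 to 0.97) and Hoxd12 by 0.65 (0.55 to 0.74), whereas Hoxa11 was at -0.20 (-0.27 to -0.13) and Hoxd11 at -0.20 (-0.31 to -0.09). BMP pathway genes had a median of 0.21 (-0.17 to 0.12) and 9 of 14 higher, with Bmp2 at 0.85 (0.66 to 1.06). Neural crest and glia genes had a median of 0.48 (-0.24 to 0.44) and 4 of 6 higher, with Sox10 at 1.05 (0.56 to 1.62), a call lost in 3 of 7 other settings. Imprinted and mitochondrial genes were both at 0.05, just above ranges of -0.21 to 0.03 and -0.22 to 0.03, ranges that lie mostly below 0, with 7 of 12 and 9 of 13 members higher. With deposited TPM both were at 0.19 and the BMP list at 0.35, but most lists that were not called also moved up under that setting.

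Ridge, ectoderm, early embryonic, glycolytic and ribosomal protein lists were lower in replicate 2 by the median log2 difference of their members, again not in every member. This differs from the change in a list's median TPM. That median rose from 14.5 to 21.6 for surface ectoderm and from 109 to 119 for early embryonic genes. It fell for the ridge, glycolysis and ribosomal protein lists. Early embryonic genes had a median of -0.44 (-0.24 to 0.06) with 7 of 8 lower, including Lin28a (-1.63, -1.72 to -1.53), Trim71 (-1.02, -1.12 to -0.93) and Mycn (-0.78, -0.82 to -0.75), while Hmga2 was at 0.18 (0.14 to 0.22). Apical ridge genes had a median of -0.40 (-0.15 to 0.31) with 9 of 12 lower, including Fgf8 (-0.54, -0.64 to -0.45) and Fgf4 (-1.19, -1.56 to -0.87), whereas Fgf9 was at 0.98 (0.69 to 1.29) and Fgf17 at 0.49 (-0.20 to 1.24). Surface ectoderm genes had a median of -0.23 (-0.12 to 0.19) with 11 of 16 lower, or 0.03 when scaled to the spike-ins. Its keratins moved apart: Krt8 and Krt18 were at -0.68 (-0.78 to -0.57) and -0.70 (-0.82 to -0.59), but Krt14, Krt15 and Krt5 at 2.01 (1.81 to 2.24), 2.10 (1.72 to 2.57) and 0.93 (0.81 to 1.04). FGF response genes were at -0.25 (-0.19 to 0.10; 7 of 11 lower) and WNT genes at -0.18 (-0.16 to 0.14; 8 of 12 lower), or 0.01 and 0.08 when scaled to the spike-ins. The WNT call was lost with deposited TPM (0.00). Fgf10 was at -0.74 (-0.85 to -0.63) and the WNT effector Tcf7 at -0.92 (-1.03 to -0.82). All 12 glycolysis genes were lower, with a median of -0.43 (-0.22 to 0.03) and Eno1 at -0.54 (-0.55 to -0.53). Of the ribosomal protein genes 73 of 74 were lower, with a median of -0.35 (-0.15 to -0.05). Erythroid genes had a median of -0.28 (-0.18 to 0.11) with 12 of 14 lower, and early response genes -0.40 (-0.20 to 0.32) with 7 of 8 lower, although Jun was at 0.75 (0.67 to 0.84). Hoxd, Hoxb and Hoxa cluster lists had medians of -0.60 (-0.19 to 0.25), -0.43 (-0.24 to 0.48) and -0.20 (-0.19 to 0.27), the last at 0.06 when scaled to the spike-ins, with 7 of 9, 9 of 9 and 7 of 11 genes lower. Within the Hoxd cluster, Hoxd3, Hoxd4, Hoxd9 and Hoxd10 were at -1.05, -1.07, -0.60 and -0.55. Noncoding RNAs of the Hox clusters had a median of -0.40 (-0.27 to 0.50) with 4 of 7 lower. With deposited TPM 11 of these lists stayed apart but lay closer to 0: Hoxd -0.40, early embryonic and glycolysis -0.28, apical ridge -0.24, ribosomal -0.20, Hoxb and early response -0.18, erythroid -0.13, FGF response -0.10, surface ectoderm -0.08 and Hoxa -0.06. That setting also moved every uncalled list upward except the macrophage and heart lists. Limb mesenchyme, for example, went from -0.04 to 0.12 and proximal genes from -0.02 to 0.14. A value closer to 0 is thus not by itself a weaker call. Scaled to the spike-ins, ribosomal genes were at -0.09 and erythroid genes at -0.02, with random lists shifted alike.

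**Figure D3:**
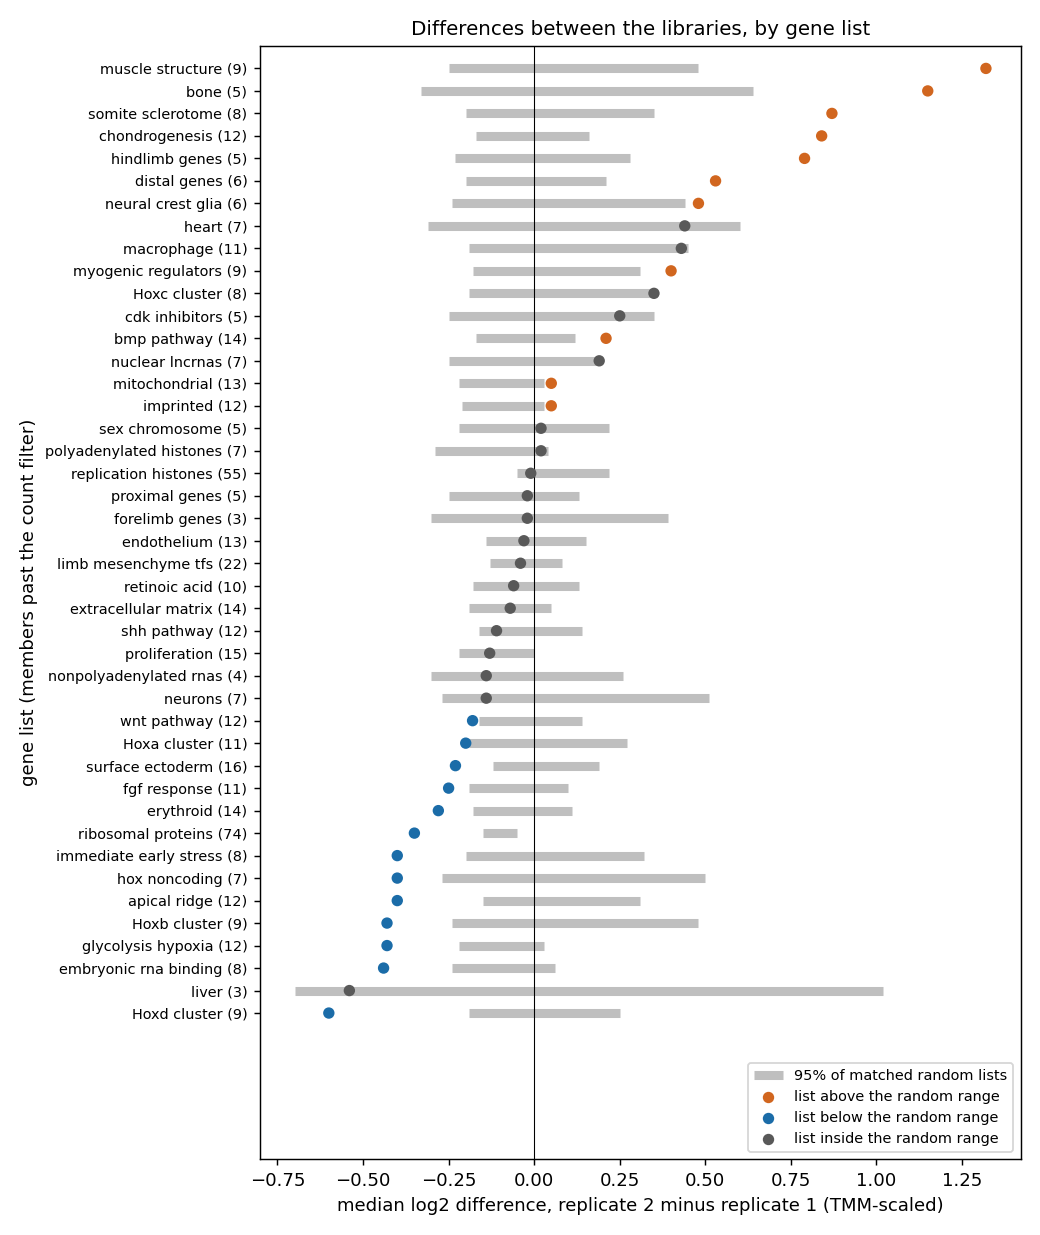
Median log2 difference (replicate 2 minus replicate 1) of each fixed list, with grey bars for 95% of random lists matched on expression. Points right of their bars include muscle structure at 1.32 and chondrogenesis at 0.84, and points left of them the Hoxd cluster at -0.60 and glycolysis at -0.43.

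In all, 11 of 43 lists were higher and 13 lower in replicate 2 than random lists of like expression. The other lists lay inside their ranges: limb mesenchyme -0.04, proximal -0.02, sonic hedgehog -0.11, retinoic acid -0.06, endothelium -0.03, macrophage 0.43, neurons -0.14, heart 0.44, liver -0.54, proliferation -0.13, kinase inhibitors 0.25, polyadenylated histones 0.02, replication histones -0.01, RNAs without poly(A) tails -0.14, nuclear noncoding RNAs 0.19, sex chromosome genes 0.02, matrix -0.07 and Hoxc cluster 0.35. Of these, heart genes stood apart at a mean count of 50 or more (0.85). Liver genes did so without the filter (-1.12) and with deposited TPM (-0.32). Hoxc genes did so without the filter (0.52) and when matched on expression and length (0.35). Sonic hedgehog, macrophage, polyadenylated histone and nuclear noncoding lists stood apart under some settings. The sex chromosome list mixes Xist, at 0.50 (0.44 to 0.55), with Y-linked genes such as Eif2s3y, at -0.17 (-0.31 to -0.04), so its median does not measure the share of the sexes. Neural tube genes had too few members past the count filter. The genes with the smallest log2 difference after the pseudogene Rpl21-ps15 (201 and 0 counts, shared with Rpl21) were Foxf1 (-3.23, -3.97 to -2.74), Upk3b, a gene of urothelium and mesothelium (423 and 120 counts), the GATA factor Gata5 (-1.88, -2.35 to -1.50) and Lin28a. Above Myod1, Col9a2, Col9a3 and Myog stood a row with no name in the annotation used here, ENSMUSG00000090407.1, with 0 and 226 counts. Scaling to the spike-ins moved the median difference of all genes to 0.264, and the differences given are relative to TMM scaling.

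Transcript estimates were compared last. Of 7111 protein-coding genes with a TPM of 5 or more in both libraries and at least 2 annotated transcripts, 6679 (93.9%, 95% exact binomial interval 93.3 to 94.5) had the same leading transcript in both. Among key genes, the leading transcript of Pitx1 took 90.5% ± 1.9 of its TPM and that of Gli3 62.1%, whereas Tbx4 went from 67.4% in replicate 1 to 88.3% in replicate 2 and Hoxa13 from 68.6% to 100%. Hoxa13 was outside the set above, at 2.25 TPM and 107 counts in replicate 1. Its second transcript was at only 0.71 TPM there, so its change rests on few reads. Prrx1 divided its TPM among 5 transcripts, the leading one at 33.0% ± 0.1.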

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

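Rows with numeric identifiers, which the report's comparisons do not use, held 68.9 counts in replicate 1 and 59 in replicate 2. Both lie above the 3 counts that an observed 0 allows. In each library 6 of these rows had counts, the highest being 25.9 counts in replicate 1 and 27 in replicate 2. What these rows stand for is not given in the sources used here, and no explanation was tested.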

How the results depend on the processing

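The scaling to spike-in counts was chosen after seeing the data; every other alternative was fixed before the data were examined. Counts of expressed genes (9987 to 16758), called pairs (26 to 31 of 32), lists higher in replicate 2 (10 to 13) and lists lower (13 to 14) stayed within 1.5 times their values under every alternative run. With each library alone, the Hoxa difference was 2.85 to 3.25 and the Hoxd difference 2.69 to 3.37, and in replicate 1 alone neither passed the threshold. Log2 ratios in single libraries ran from -0.64 to 0.55 for Tbx5 to Tbx4, -0.15 to 0.23 for Sox9 to Col2a1 and -0.26 to 3.32 for Pax3 to Myod1. They ran from -0.85 to 0.17 for Col1a1 to Col2a1 and -0.06 to 0.99 for Lin28b to Lin28a. Against expressed genes only, 7 of 42 lists were high and 8 low. This setting limited list members and background together, so the move cannot be put down to either one. With posterior mean TPM, 1 list was low. Pearson r was 0.986 with a pseudocount of 0.1 and 0.991 with no filter or a mean count of 50 or more. The coefficient of variation was 0.174 with no filter and 0.157 at a mean count of 50 or more. Shared leading transcripts were 91.8% at a TPM of 1 or more and 95.6% at 20 or more. Scaled to the spike-ins, surface ectoderm was at 0.03, FGF response at 0.01, WNT at 0.08 and the Hoxa cluster at 0.06, since this scaling shifts every gene, random lists included, by about the same amount and so cannot test a call; WNT genes were at 0.00 with deposited TPM, where they no longer stood apart, and the cause was not tested. Of the other list differences, 279 kept their call, 11 gained one and 5 lost it. For r, the coefficient of variation and transcripts, no cause was tested. Leaving out a library is impossible for differences between the 2 libraries. No paired analysis was possible because there is 1 group.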

Other observations

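Globin genes differed among themselves between the pools. The embryonic beta-globins Hbb-bh1 and Hbb-y were at -0.78 (-0.81 to -0.76) and -0.31 (-0.32 to -0.30) on the log2 scale (replicate 2 minus replicate 1), the adult-type genes Hbb-bt and Hbb-bs at 0.81 (0.74 to 0.88) and 0.57 (0.37 to 0.77). Noncoding RNAs of the Hox clusters also moved apart: Hottip, beside Hoxa13, was at 2.34 (1.85 to 3.02), Hotair at 1.67 (1.07 to 2.48) and Hoxa11os at 0.70 (0.64 to 0.77), whereas Hoxd3os1 was at -0.89 (-1.11 to -0.68). Antisense RNAs cannot be told from overlapping genes without strand. Among imprinted genes, the growth inhibitor Cdkn1c was at 0.76 (0.72 to 0.80) and Dlk1 at -0.67 (-0.73 to -0.61).

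The tests of developmental stage, of trunk tissue and of the share of hindlimb were chosen after the results were seen. The tests of GC content and length, of spike-in length and of pseudogenes were written before their values were computed, but with the uncorrected differences known. For ribosomal protein genes, the first such test removed most of the difference. Refitting without the genes themselves, which left -0.10, and the demand that matched lists also contain them were added after that result was seen, and they changed its reading to open. The part of a difference that the trend itself supplies was also added after the results were seen, and it changed the reading for hindlimb genes from open to argued against. The test of distal Hox genes first took the 3 that were higher and was then widened to all 5.

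Over the 36 genes of the cartilage, muscle structure, myogenic and distal lists, the median log2 difference was 0.68 in favour of replicate 2. A bias with GC content, length or expression is argued against, since removing these trends left 0.64 (bootstrap interval 0.28 to 1.22) and the trends supply 0.07 (0.06 to 0.08). More trunk tissue stays open. The early somite genes Tcf15, Meox1, Pax3 and Lbx1 had a median of -0.14 while the whole somite list was at 0.87. The 5 distal Hox genes had a median of 0.65, with Hoxa11 and Hoxd11 both at -0.20. These Hox genes are part of the pattern itself and decide nothing. Foxf1, Upk3b (a gene of urothelium and mesothelium) and Gata5 were among the genes most lowered in replicate 2, as given above. They were not part of the trunk test, and the tissue they came from was not tested. A later mean stage of replicate 2 is a hypothesis that stays open and untested by independent values, since these were seen first: early embryonic genes had a median of -0.44, and Hbb-bh1 over Hbb-y changed by -0.48 (-0.50 to -0.45), with Hba-x over the Hba-a genes at -0.11 (-0.14 to -0.09). The labels give both pools the same age and there is 1 library per pool, so stage, dissection and library batch may each contribute.

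Hindlimb genes had a median difference of 0.79. A larger share of hindlimb in replicate 2 would lower Tbx5, which was at -0.27 (-0.34 to -0.19) but at percentile 12.4 among 500 genes of like expression, so this cannot be told apart from the general spread. A bias with GC content, length or expression is argued against as the whole cause: these trends supply 0.02 (0.01 to 0.04) of the difference, and the median after their removal was 0.83, with a bootstrap interval of 0.08 to 1.13 over 5 unlike genes. A candidate explanation is a difference in stage or in the share of fore- and hindlimb, and these data do not separate them.

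Ribosomal protein genes had a median difference of -0.35. A length bias that acts on spike-ins and sample RNA alike is argued against, since the spike-ins' trend predicts 0.03 (-0.01 to 0.08) at these genes' length. The spike-ins cannot show a length trend that arises in the sample RNA itself. Reads moved to pseudogenes named after ribosomal protein genes are argued against, since these 246 summed were at -0.35 themselves. Pseudogenes under other names were not summed. GC content combined with expression and length stays open. The trends supply -0.27 (-0.29 to -0.25) and removing them left -0.09, yet removing expression, GC content or length singly left -0.25, -0.40 and -0.30, and lists matched on expression and length still lay above these genes. No biological explanation was tested.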
